A study of Danio rerio with 6 samples.

How the data were processed

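RNA was taken from kidney marrow suspensions of 6 adult zebrafish, 3 grna-/- and 3 grna+/+ siblings, with 1 marrow per library, per the labels' protocols. The marrows were dissected after blood was drawn from the heart, triturated and passed through a strainer, so no cell type was sorted. Samples with an RNA integrity number above 8 were used, and libraries were made from 50 ng of RNA with a stranded messenger RNA kit. They were sequenced as 75 bp single reads, per the series' design text. Genotype came from the genotype label of each sample and the replicate number from its title. Replicates were separate fish, so p-values measure the spread between fish of one genotype. No label gives the sex, age or clutch of a fish.

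The authors deposited 1 table of TPM, with 15292 genes and 1 column per library. Per the submitters' processing notes, featureCounts, Subread and DESeq2 1.26.0 were used with the genome builds GRCz10 and danRer10. Which tool made the TPM values, and whether strand was used in counting, is not given in the sources used here. TPM divides the reads of a gene by its length and scales each library to the same total, so a rise of abundant genes lowers the others. A row named Total names no gene. It was read as the number of reads counted per library, 11080875 to 14075134, left out of all tests and used only as the depth.

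Depth was checked from the values. For each gene, the 6 TPM values divided by one factor per library stood in ratios of whole numbers, which gave whole reads at a relative tolerance of 1e-09 for all 11875 genes above 0 in all 6 libraries. When values of 437 such genes were moved at random by up to 0.1%, 3 still came out whole. The other genes came out whole too, but 1256 are at 0 throughout and cannot fail, and 35 of 63 moved genes above 0 in 3 to 5 libraries came out whole, so these genes test little. The recovered reads summed to 99.27% to 99.30% of the Total row. On simulated data, 96.62% of genes were recovered exactly, and 98.16% of genes with reads in 3 or more libraries. A factor common to the 6 libraries of a gene cannot be seen this way, so recovered reads served as an added alternative and for the floor of 3 reads, which covers counting error only. The symbols of 15055 genes (98.5%) were found in a RefSeq gene table of assembly GRCz12tu. That table was used only for names and for which genes lie near grna, and no coordinates are printed because the build differs from that of the authors.

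Genes were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with genes kept at a mean of at least 1 TPM over the 6 libraries (10750 genes). The model held genotype alone, with moderated variances that followed a trend on mean expression. Tests were two-sided, and Benjamini-Hochberg adjusted p below 0.05 was called. Fold changes are on the log2(TPM + 1) scale, grna-/- minus grna+/+, which understates changes of low genes. "Rose" and "fell" are used of called genes only. Folds on mean TPM are given as such. Of the called genes, 68 rises and 44 falls were of at least 2-fold on the log2 scale. The median log2 fold change of all tested genes was 0.07.

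The plan held other tests in case the table gave raw counts, and as it gave TPM the plan for TPM was followed. The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are grna and its paralogs, the 12 largest rises and 12 largest falls among called genes with a named symbol and no overlap between the genotypes, and up to 4 members of each list with the smallest p. Of the 124 called genes, 23 had provisional or clone symbols and are outside that rule. Results of some list members that the rule takes in are not reported here. Other genes are said to have been picked after their values were seen.

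The 28 gene lists held markers of blood lineages, kidney, vessel, stroma, muscle, liver and pancreas, and gonad, and pathways tied to granulins, inflammation or RNA quality. Lists were tested with camera from limma at a preset correlation of 0.01 between genes, and 25 lists had at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Counts of members are given over all genes and adjusted over the list alone.

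The titles number the fish 1 to 3 in each genotype, and no label says what a number shares. Over all tested genes, the deviations of same-numbered fish from their group means correlated at 0.136, 0.153 and 0.237. Each exceeded the bound of 0.1 set for this check, so the numbers may pair the fish, as a reading of the data and not of the design. With 3 fish per genotype, same-numbered fish can match best by chance, so the check does not settle this. Centring ties the other pairs to these values, so they add no support. The model without the block stayed the reported one. Blocked values are printed where they change the call of a list or of a gene named by the rule. These correlations are across genes, which are not independent replicates.

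No library was a duplicate of another: chi-square per degree of freedom on recovered reads was between 26.7 and 160 for all pairs. The tests were tried on data simulated for the comparison of grna-/- with grna+/+ over 10705 tested genes. Of 50 genes each, 20% of 2-fold rises, 32% of 2-fold falls, 80% of 4-fold rises and 68% of 4-fold falls were called. 10 unchanged genes were called beside them, and 0 genes were called when nothing was changed, where 5.3% had an unadjusted p below 0.05. Each gene was simulated independently of the others, so these rates leave out genes that move together between fish. Alternatives covered the pseudocount (0.1 and 5), the filter (none and 5 TPM), scaling, variance moderation, library weights, the replicate block, the list test and leaving out each library. An alternative chosen after seeing the data applied voom from limma to the recovered reads of genes with a mean of at least 10 reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for read recovery and plots.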

Results

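Messenger RNA was sequenced from the kidney marrow of 6 adult zebrafish, 3 with both copies of grna mutated (grna-/-) and 3 of their grna+/+ siblings. Kidney marrow is the site of adult blood formation in fish, and it holds erythroid, myeloid, lymphoid and thrombocyte cells together with kidney tubules, vessels and stroma. grna encodes a zebrafish granulin, a secreted protein that is also found in lysosomes. Each library came from 1 fish, and the table gave TPM, transcript abundance corrected for gene length and scaled to the same total in each library, for 15292 genes. The reads counted per library were 13388527, 12297877 and 13282421 in grna+/+ replicates 1 to 3 and 11080875, 14075134 and 12257996 in grna-/- replicates 1 to 3. Between 12842 and 13048 genes had a value above 0 in a library.

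The single comparison in the design, grna-/- against grna+/+, asks how the loss of this granulin alters gene expression in the marrow, with myeloid differentiation as the stated interest of the study. grna itself was at 151.2, 134.7 and 145.6 TPM in the grna+/+ libraries and at 65.2, 73.98 and 71.92 TPM in the grna-/- libraries. The mean fell from 144 ± 8.40 to 70.4 ± 4.59 TPM (SD, n = 3 each), 48.9% of the grna+/+ mean. limma gave a log2 fold change of -1.02 (SE 0.129, adjusted p = 0.0186). All 3 grna-/- values lay below all 3 grna+/+ values, so the transcript agreed in direction with the genotype on each label. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest it can give with 3 against 3. The labels do not say which part of the gene was altered. When 1 library was left out, the log2 fold change stayed between -1.07 and -0.97. The adjusted p then rose above 0.05 without grna+/+ replicate 3 (0.0836) and without grna-/- replicate 1 (0.093), 2 (0.0616) or 3 (0.0526).

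None of the other granulin genes tested passed in limma. The paralog grnb was at 11.2 ± 1.51 TPM in grna+/+ and 11.6 ± 1.096 TPM in grna-/- (adjusted p = 0.907). The short granulin gene grn1 was at 303 ± 96.3 TPM in grna+/+ and 280 ± 292 TPM in grna-/- (adjusted p = 0.65), where 1 library reached 615.9 TPM and the others 132.8 and 90.39 TPM. grn2 averaged 42.7 ± 18.3 and 64.1 ± 75.2 TPM (adjusted p = 0.992). grn1 and grn2 are near-identical copies that can share reads, so their values are uncertain. grnas, at 0.759 ± 0.416 and 0.434 ± 0.0878 TPM, lay below the expression filter and was not tested.

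Across the marrow, 71 genes rose and 53 fell in grna-/- among 10750 genes tested. The 12 largest rises among named genes were cyp7a1, ddc, lgals2b, slc51a, dio2, mao, slc25a38a, lmod2a, csad, irs2a, igfbp5a and slc16a12b. cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 1.02 ± 1.499 to 290 ± 147 TPM (SD, n = 3 each), a log2 fold change of 7.29 (SE 0.514, adjusted p = 0.0017). ddc, the aromatic amino acid decarboxylase that makes dopamine and serotonin, rose from 0.494 ± 0.791 to 206 ± 106 TPM, and mao, the monoamine oxidase that breaks these amines down, from 7.09 ± 1.57 TPM by a log2 fold change of 4.16 (SE 0.297). slc51a, a subunit of a steroid and bile acid exporter, rose from 3.76 ± 3.04 to 125 ± 39.7 TPM. dio2, the deiodinase that activates thyroid hormone, rose from 12.49 ± 2.02 to 278 ± 130 TPM. The galectin gene lgals2b rose 59.9-fold on mean TPM (log2 fold change 5.51, SE 0.42).

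Among the smaller of these rises, slc25a38a, which carries glycine into mitochondria for heme synthesis, rose from 0.538 ± 0.0720 to 14.3 ± 7.50 TPM. csad, an enzyme of taurine synthesis, rose from 11.8 ± 4.72 to 79.7 ± 34.6 TPM. irs2a, an insulin receptor substrate, rose 4.29-fold on mean TPM, and igfbp5a, an insulin-like growth factor binding protein, rose 7.03-fold. The monocarboxylate transporter family gene slc16a12b rose 4.24-fold. The leiomodin gene lmod2a was at 0 in all grna+/+ libraries and averaged 8.11 ± 5.92 TPM in grna-/-. It was at least 38.9-fold higher, taking 3 reads over the grna+/+ group as the floor. Of its 112 grna-/- reads 64 came from replicate 1, and the bound is 23.7-fold without that library.

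The 12 largest falls were f13a1a.1, apoeb, ugt5g1, vtg6, hamp, gig2j, slc25a15a, cyp1c2, tcf21, gig2g, lpar5b and stab2. f13a1a.1, the A subunit of coagulation factor XIII, fell from 178 ± 189 to 0.721 ± 0.659 TPM, a log2 fold change of -6.21 (SE 0.668, limma adjusted p = 0.009). apoeb, an apolipoprotein E gene, fell from 319 ± 199 to 15.4 ± 4.40 TPM (log2 fold change -4.07, SE 0.481, adjusted p = 0.0126). The glucuronosyltransferase gene ugt5g1 fell from 77.3 ± 30.9 to 4.67 ± 2.13 TPM. The yolk protein gene vtg6 fell from 35.8 ± 12.4 to 3.19 ± 0.596 TPM. It has near-identical copies, so its level is uncertain. hamp, which encodes the iron hormone hepcidin, fell from 14.7 ± 11.7 to 0.753 ± 0.905 TPM, with 28.09 TPM in grna+/+ replicate 2 against 6.23 and 9.72 TPM in replicates 1 and 3. Its call was lost under 14 of 18 alternative settings, over which the log2 fold change ran from -4.42 to -1.63. The virus-inducible genes gig2j and gig2g fell 7.75-fold and 3.92-fold on mean TPM. They too belong to a family of similar copies. slc25a15a, a mitochondrial ornithine carrier, fell 5.86-fold, and the cytochrome P450 gene cyp1c2 fell 5.80-fold. tcf21, a transcription factor of podocytes and mesenchyme, fell from 15.5 ± 4.18 to 2.85 ± 0.701 TPM. The lysophosphatidic acid receptor gene lpar5b fell 3.93-fold and the scavenger receptor gene stab2 fell 3.69-fold.

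**Figure D1:**
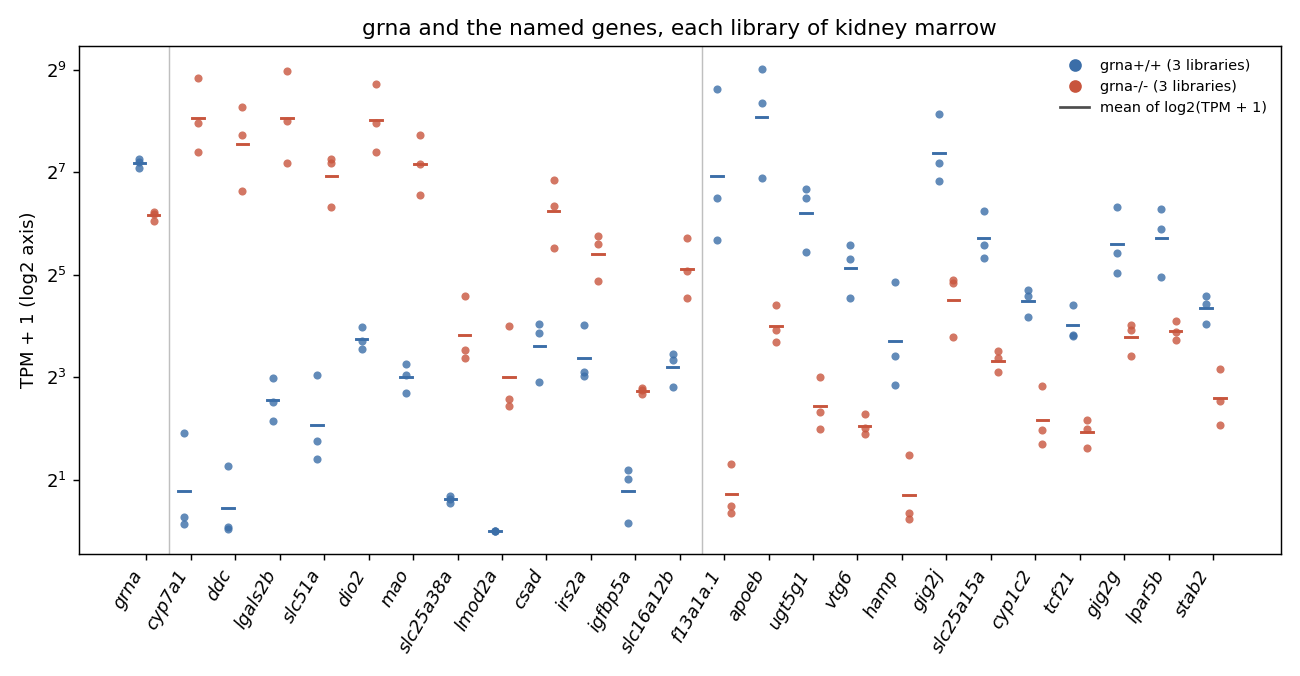
TPM + 1 on a log2 axis for grna and the 24 named genes, with 1 point per library (blue grna+/+, red grna-/-, 3 libraries each) and a bar at the mean of log2(TPM + 1). The 3 grna-/- points lie on one side of the 3 grna+/+ points for every gene shown, with cyp7a1 at 0.104, 2.75 and 0.204 TPM in grna+/+ and at 248, 453 and 167 TPM in grna-/-.

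All 124 genes had the 3 values of one genotype on one side of the other 3. This held for 24.6% of the genes tested, where 10% is expected per gene by chance for 3 against 3. Genes move together, so the share can lie far from 10% by chance. It was not computed for other groupings of the libraries. With the replicate numbers as a block, 271 genes passed (149 up, 122 down). The count depended on single libraries: it was 204 without grna+/+ replicate 1, 84 without replicate 2 and 16 without replicate 3, and 33, 18 and 41 without grna-/- replicates 1, 2 and 3. Of the 24 genes named for their size of change, 9 were called under every setting run, namely cyp7a1, ddc, lgals2b, slc51a, dio2, mao, slc25a38a, ugt5g1 and vtg6. The other 15 kept their direction in all settings, but each lost its call in at least 1. Calls were lost most often for hamp (14 of 18 settings), lpar5b (12 of 18), gig2g (11 of 18) and irs2a (10 of 18).

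Erythroid genes were higher in grna-/-. Of 33 tested members of the erythroid list, 6 rose, none fell and 31 had a fold change above 0, with a median log2 fold change of 0.80 (camera adjusted p = 2.52e-12). With an estimated correlation between genes the adjusted p was 0.595. Adjusted over the list alone, 19 members passed, all upward. With the replicate block, 9 members were called over all genes, each of them upward. The members that rose were nt5c2l1, ank1a, sox6, creg1, alas2 and epb41b. alas2, the first enzyme of erythroid heme synthesis, rose from 323 ± 91.5 to 759 ± 122 TPM. ank1a, the ankyrin of the red cell membrane skeleton, rose from 12.3 ± 2.95 to 32.9 ± 3.03 TPM, and epb41b, a protein 4.1 gene of the same skeleton, from 65.8 ± 20.4 to 162 ± 9.02 TPM. sox6, a transcription factor of erythroid maturation, rose from 2.07 ± 0.699 to 7.58 ± 1.25 TPM, and nt5c2l1 rose from 78.2 ± 23.0 to 260 ± 41.3 TPM. The globin genes ba1l and hbaa1 together took 4.15%, 2.06% and 4.93% of TPM in the grna+/+ libraries and 7.92%, 9.12% and 8.03% in the grna-/- libraries, although neither passed by itself (adjusted p = 0.0838 and 0.0818). ba1l and hbaa1 were picked after their values were seen; they have similar copies, and reads can be split among them. None of the erythroid members was called without grna+/+ replicate 3 or without grna-/- replicate 1 or 2, while the list median stayed between 0.55 and 1.01 when any 1 library was left out and was 0.479 with library weights (camera adjusted p = 0.000212). epb41b was picked after its values were seen and was not followed over the alternative settings. Of the other members that rose, alas2 lost its call most often, under 11 of 18 alternative settings, and nt5c2l1 least often, under 3. The list of heme synthesis and erythroid iron uptake was not called (median 0.05, adjusted p = 0.195), but its adjusted p was 0.00472 without grna+/+ replicate 3 and 0.0189 without grna-/- replicate 1, both upward. The adjusted p was 0.717 with an estimated correlation and all 6 libraries. Among its 18 tested members slc25a38a and alas2 rose, also adjusted over the list alone, while fth1a (adjusted p = 0.292) and tfr1a (adjusted p = 0.313) did not pass.

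Cell cycle genes were slightly higher as a group. None of 45 tested members was called by limma, over all genes or adjusted over the list alone, but 44 had a fold change above 0 and the median was 0.37 (camera adjusted p = 9.15e-07). With an estimated correlation the adjusted p was 0.658. cdc6, which loads the replication helicase, averaged 10.97 ± 3.44 TPM in grna+/+ and 19.0 ± 2.36 TPM in grna-/- (limma adjusted p = 0.186), and dut, which removes dUTP, 69.8 ± 13.3 and 97.5 ± 7.78 TPM (adjusted p = 0.215). The median was 0.20 without grna+/+ replicate 2, whose cell cycle level was the lowest of the 6 libraries.

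Neutrophil genes were lower as a group. None of 24 tested members was called over all genes, 6 were lower adjusted over the list alone, and 21 had a fold change below 0, with a median of -0.51 (camera adjusted p = 3.71e-08). The adjusted p was 0.595 with an estimated correlation. With the replicate block, 5 members were called down over all genes. Without grna-/- replicate 2, the lowest of the 6 libraries for this list, the median was -0.323 (adjusted p = 2.69e-06 at the preset correlation), and without grna+/+ replicate 2 it was -0.635. The lectin-like gene illr4 averaged 790 ± 102 TPM in grna+/+ and 314 ± 128 TPM in grna-/- (limma adjusted p = 0.0515, and 0.0144 with the replicate block). The metalloproteinase gene adam8a averaged 757 ± 160 and 324 ± 88.7 TPM (adjusted p = 0.0567, and 0.0461 with the block). The granule proteoglycan gene srgn averaged 3793 ± 427 and 2313 ± 522 TPM (adjusted p = 0.0949, and 0.0487 with the block), and timp2b, an inhibitor of metalloproteinases, 475 ± 378 and 98.0 ± 39.8 TPM (adjusted p = 0.117). The most widely used neutrophil markers differed less: mpx averaged 1305 ± 450 and 1234 ± 536 TPM and lyz 31280 ± 4186 and 25020 ± 7980 TPM, with adjusted p of 0.89 and 0.405. These 2 genes were picked after their values were seen. Of the 27 genes on the list, 5 stand on other lists as well.

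Genes for the phagocyte oxidase, granules and motility were lower as a group (20 tested, none called, 4 lower adjusted over the list alone, median -0.16, camera adjusted p = 0.00206). The call was lost with an estimated correlation (adjusted p = 0.617), and without grna-/- replicate 2 the median was -0.093 and the adjusted p 0.0802 at the preset correlation. The oxidase subunit gene ncf1 averaged 1025 ± 428 TPM in grna+/+ and 434 ± 104 TPM in grna-/- (limma adjusted p = 0.117, and 0.0457 with the replicate block). ncf4 had an adjusted p of 0.12 and the integrin activator gene fermt3b of 0.116. Quantile normalization ended the call of this list (median -0.061, adjusted p = 0.0763).

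Among 27 tested myeloid transcription factors, cebpa alone was called, and it fell from 1067 ± 229 to 555 ± 47.0 TPM (log2 fold change -0.92, SE 0.16, limma adjusted p = 0.0457). This C/EBP factor is required for granulocyte formation. Its call was lost under 10 of 18 alternative settings, though its direction was kept in each. The related cebpb averaged 1553 ± 372 and 922 ± 13.7 TPM (adjusted p = 0.0907, and 0.0463 with the replicate block), and cebpd 175 ± 49.7 and 84.1 ± 33.4 TPM (adjusted p = 0.149, and 0.0373 with the block). egr1, an immediate early gene, went the other way without passing (adjusted p = 0.09). The list as a whole was not called (median -0.12, camera adjusted p = 0.153), and adjusted over the list alone 1 member was higher and 3 lower. Of its 27 tested members, 18 stand on other lists, and without such members the camera adjusted p was 0.000233 at the preset correlation. The members left include the related cebpa, cebpb, cebpd and cebpg. The list as written had an adjusted p of 0.595 with an estimated correlation and 0.0397 without grna+/+ replicate 2 at the preset one.

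Inflammatory response genes were lower as a group (22 tested, none called, 4 lower adjusted over the list alone, median -0.76, camera adjusted p = 1.57e-05, or 0.595 as an adjusted p with an estimated correlation). One library set much of this level. The list mean was 1.28 in grna+/+ replicate 2, as log2 from the mean of all libraries for each gene, against -0.17 and 0.10 in replicates 1 and 3. It was -0.50, -0.53 and -0.18 in the grna-/- libraries. The median was -0.38 without that library (camera adjusted p = 0.000564). The chemokine gene cxcl8b.1 was at 24.82, 145.9 and 32.71 TPM in grna+/+ and at 7.778, 4.767 and 7.051 TPM in grna-/- (limma adjusted p = 0.0712, and 0.0437 with the replicate block). socs3b, a suppressor of cytokine signaling, averaged 246 ± 113 and 85.7 ± 24.4 TPM (adjusted p = 0.0922, and 0.0212 with the block). hif1ab averaged 203 ± 50.7 and 114 ± 11.7 TPM (adjusted p = 0.0895) and the flagellin receptor gene tlr5b had an adjusted p of 0.15.

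**Figure D2:**
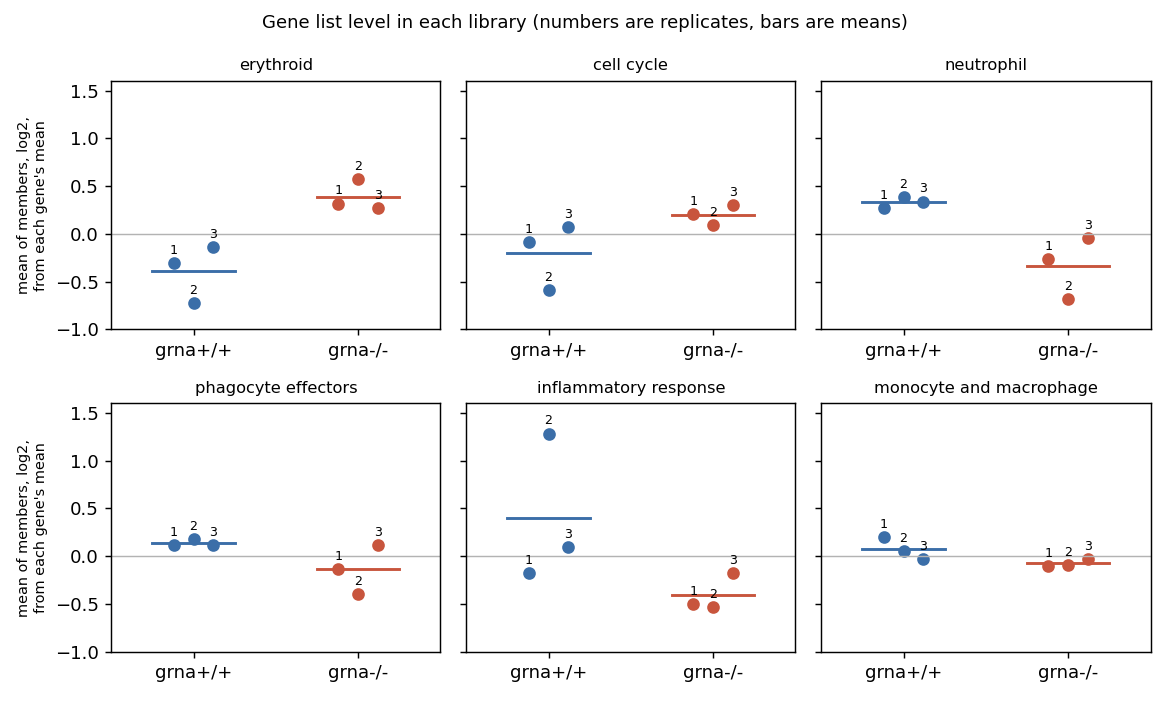
Mean level of 6 gene lists in each library, on the y axis as log2 from the mean of each gene over the 6 libraries, for grna+/+ (blue) and grna-/- (red); points are libraries numbered by replicate and bars are group means. The 3 grna-/- libraries lie above the grna+/+ libraries for the erythroid and cell cycle lists and below them for the neutrophil list, and grna+/+ replicate 2 stands at 1.28 for the inflammatory list.

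The macrophage list was not called (25 tested, camera adjusted p = 0.518). Its median was 0.11 and its mean -0.15, since apoeb fell while 13 of the 25 members had a fold change above 0. The macrophage marker mpeg1.1, picked after its values were seen, averaged 90.7 ± 16.96 TPM in grna+/+ and 113 ± 17.7 TPM in grna-/- (limma adjusted p = 0.395). The cathepsin gene ctss2.1 (adjusted p = 0.07), the invariant chain gene cd74b (0.131) and ms4a17a.11 (0.142) did not pass. Adjusted over the list alone, 1 member was higher and 3 lower. Among 18 thrombocyte genes f13a1a.1 fell, and none rose; adjusted over the list alone, 1 was higher and 2 lower. The list had a median of -0.14 and a camera adjusted p of 0.0591, or 0.0494 with the replicate block, 0.0295 without grna+/+ replicate 2 and 0.017 without grna-/- replicate 1. Its adjusted p was 0.595 with an estimated correlation. gp1bb, a platelet receptor subunit, had a log2 fold change of 1.12 (SE 0.258, limma adjusted p = 0.089, and 0.0415 with the block), opposite in direction to the list. itgb3b (adjusted p = 0.153) and rap1b (0.178) did not pass.

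The lymphoid, dendritic and progenitor lists were not called, and no member passed over all genes. Adjusted over the list alone, 1 member was higher in each of the cytotoxic, dendritic and progenitor lists and none passed in the T cell and B cell lists. The T cell list (20 tested) had a median of -0.07 and a camera adjusted p of 0.234, with lat, cd247, sla2 and ccr9a nearest to the threshold (limma adjusted p from 0.177 to 0.276). The natural killer and cytotoxic cell list (16 tested) had a median of 0.25 and an adjusted p of 0.195. Its leading members were ccl34b.4 (0.089), prf1.3 (0.196), ccl38.6 (0.325) and nkl.1 (0.332). The B cell list (16 tested) had a median of 0.02, a mean of -0.09 and an adjusted p of 0.461, and cd22, cd40, blnk and pax5 all had adjusted p above 0.05. The dendritic cell and antigen presentation list (7 tested) had a median of -0.11 and a mean of -0.003, and the test pointed upward without passing (adjusted p = 0.956). The stem and progenitor cell list (18 tested) had a median of 0.19 and an adjusted p of 0.31, with lmo2, fli1a and tal1 not called.

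Of 34 tested members of the kidney tubule and glomerulus list, 2 fell and none rose. With the replicate block, 3 members were called up and 2 down. podxl, which encodes the podocyte surface protein podocalyxin, fell from 25.7 ± 2.26 to 12.9 ± 1.85 TPM (log2 fold change -0.94, SE 0.171, limma adjusted p = 0.0491). This call was lost under 11 of 18 alternative settings, with an adjusted p of up to 0.176. nphs1, which encodes nephrin, averaged 4.34 ± 0.607 and 1.51 ± 0.297 TPM (adjusted p = 0.0599), and wt1b had an adjusted p of 0.0625. Adjusted over the list alone, 1 member was higher and 5 lower. The list was not called (median 0.12, mean 0.05, camera direction down, adjusted p = 0.34). Without grna-/- replicate 2, which had the highest kidney level of the 6 libraries, the adjusted p was 0.000851 and the median -0.23. The adjusted p was 0.819 with an estimated correlation and all 6 libraries.

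Endothelial genes were lower as a group (20 tested, median -0.39, camera adjusted p = 0.000386, 1 lower adjusted over the list alone), and stab2, a scavenger receptor of sinusoidal and lymphatic endothelium, was the called member. The list's adjusted p was 0.617 with an estimated correlation and 0.0796 with library weights, where the median was -0.11. The median was -0.17 without grna+/+ replicate 1 and -0.19 without grna-/- replicate 3. cldn5b (limma adjusted p = 0.151), lyve1b (0.286) and fli1a (0.197) did not pass. Stromal and fibroblast genes were lower as a group (20 tested, none called, 1 lower adjusted over the list alone, median -0.43, camera adjusted p = 0.0337), with an adjusted p of 0.658 at an estimated correlation. This call ended without grna+/+ replicate 2 (median -0.15, adjusted p = 0.37), without grna-/- replicate 2 (-0.421, 0.0802) and without grna-/- replicate 3 (-0.335, 0.303). It also ended with genes kept at a mean of at least 5 TPM (median -0.093, adjusted p = 0.383), with no filter (-0.267, 0.0572), with library weights (0.077, 0.989), with median-of-ratios scaling (-0.493, 0.0577) and with voom (-0.522, 0.0767). cxcl12a, a chemokine that holds blood progenitors in the marrow, averaged 751 ± 65.5 and 352 ± 125 TPM (limma adjusted p = 0.0715, and 0.0201 with the replicate block). thy1 averaged 447 ± 197 and 203 ± 129 TPM (adjusted p = 0.226, and 0.0283 with the block), and bgnb and tagln did not pass.

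The liver and pancreas list was lower as a group (8 tested, median -0.79, camera adjusted p = 0.0282), with an adjusted p of 0.595 at an estimated correlation. The pancreatic elastase gene ela2l, the called member, rose from 1.03 ± 0.187 to 5.69 ± 2.19 TPM (limma adjusted p = 0.041), a call lost under 11 of 17 alternative settings. Adjusted over the list alone, 1 member was higher and 5 lower. The liver genes fabp10a (11.03 ± 5.47 and 3.36 ± 1.24 TPM, adjusted p = 0.147), cp (0.148) and tfa (0.151) did not pass over all genes. The list's call ended without grna+/+ replicate 1 (0.0685) or 3 (0.0501) or grna-/- replicate 3 (0.113). It also ended with no filter on low values (0.446, with a median of 0.008), median-of-ratios scaling (0.0577), quantile normalization (0.0554), voom (0.0549) and without members of other lists (0.0607). Muscle and gonad had 1 tested member each, tnnt3b and sycp1, and were not tested as lists. No mitochondrially encoded gene was in the table.

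Of 56 lysosome genes, the group to which granulins are tied by their location, ctsbb rose and none fell. ctsbb, a cathepsin B gene, rose from 7.14 ± 2.42 to 23.6 ± 6.12 TPM (log2 fold change 1.61, SE 0.277, limma adjusted p = 0.0454), and lost its call under 8 of 18 alternative settings. ctsc averaged 94.8 ± 12.6 and 159 ± 19.1 TPM (adjusted p = 0.0713, and 0.0445 with the replicate block), and ctsh (0.0972) and cd63 (0.134) did not pass. The list was not called (median 0.14, camera adjusted p = 0.234), and adjusted over the list alone 2 members were higher and none lower.

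Unfolded protein response genes were lower as a group (32 tested, none called, 2 lower adjusted over the list alone, median -0.20, camera adjusted p = 0.00113). With an estimated correlation the adjusted p was 0.658. Much of the size rested on grna+/+ replicate 2, the highest library for this list: without it the median was -0.045 and the adjusted p 0.0912 at the preset correlation. Quantile normalization gave a median of -0.127 and an adjusted p of 0.0554, and without grna-/- replicate 2 they were -0.136 and 0.0498. xbp1, a transcription factor of this response, averaged 1031 ± 125 and 661 ± 36.2 TPM (limma adjusted p = 0.0538). ero1a, an oxidase of the endoplasmic reticulum, averaged 35.9 ± 12.4 and 13.9 ± 1.35 TPM (adjusted p = 0.0528, and 0.0215 with the replicate block). Ribosomal protein genes were lower by a small amount (87 tested, none called over all genes or adjusted over the list alone, median -0.08, camera adjusted p = 3.84e-06). With an estimated correlation the adjusted p was 0.595, and after quantile normalization it was 0.696, with a median of -0.005. rpl32 averaged 5296 ± 327 and 4683 ± 103 TPM (limma adjusted p = 0.299). The symbol rule for this list also took in ribosomal S6 kinase genes, and rps6ka1 (0.266) and rps6kb1b (0.268) had the smallest p of its members.

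**Figure D3:**
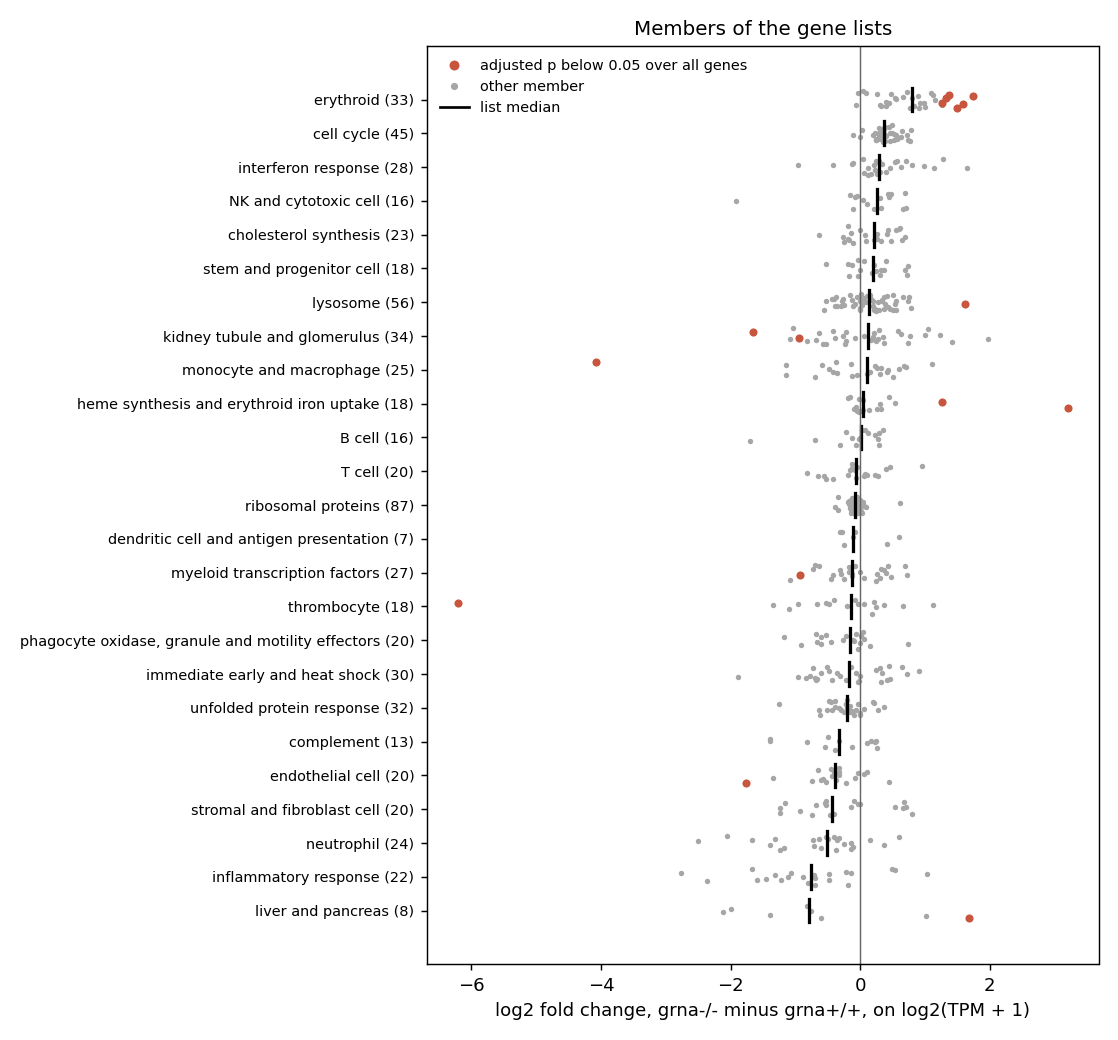
Log2 fold change (grna-/- minus grna+/+, on log2(TPM + 1), x axis) of each tested member of the 25 gene lists tested, with the number of tested members in brackets; red points passed limma over all genes, grey points did not, and black bars are list medians. The erythroid list has the highest median, 0.80, and the liver and pancreas list the lowest, -0.79.

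The remaining lists were not called with all 6 libraries and no block, and none of their members passed over all genes or adjusted over the list alone. Interferon response genes (28 tested) had a median of 0.29 and a camera adjusted p of 0.0673, or 0.0142 with the replicate block, 0.045 without grna+/+ replicate 2 and 0.00128 without grna-/- replicate 2. Its adjusted p was 0.688 with an estimated correlation. rsad2 averaged 2.68 ± 3.37 and 9.21 ± 7.04 TPM (limma adjusted p = 0.258, and 0.0166 with the block), and socs1a, mxc and gbp4 did not pass. Complement genes (13 tested) had a median of -0.33 (camera adjusted p = 0.195), cholesterol synthesis genes (23 tested) a median of 0.21 (0.343), and immediate early and heat shock genes (30 tested) a median of -0.17 (0.168). The immediate early list had a median of -0.41 and an adjusted p of 0.00029 without grna+/+ replicate 1, and an adjusted p of 0.0498 without grna-/- replicate 2. The complement list had an adjusted p of 0.0487 without grna-/- replicate 1 and 0.0269 without members of other lists. Neither was called with an estimated correlation (adjusted p = 0.717 and 0.595). c6 (limma adjusted p = 0.121), sc5d (0.175), dnajb1b (0.137) and atf3 (0.207) were among the members nearest to the threshold in these groups. In all, 2 lists were called up and 8 down of 25 tested with the preset correlation, and none of the 25 with an estimated correlation or with fry.

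Siblings of different genotype can also differ at genes near the mutation. Within 10 Mb of grna, 5 of 232 tested genes were called, against 118 of 10437 elsewhere (odds ratio 1.93, 95% interval 0.608 to 4.69, two-sided Fisher's exact test p = 0.196). With the granulin genes left out it was 4 of 231 genes (odds ratio 1.54, Fisher's exact test p = 0.34). The 5 were grna, hsd3b7, slc25a39, nfe2l1a and the provisional gene zgc:194125, named after their values were seen. hsd3b7, a bile acid synthesis enzyme, fell from 418 ± 50.1 to 187 ± 25.5 TPM. slc25a39, which brings glutathione into mitochondria, rose from 15.3 ± 5.78 to 39.1 ± 3.01 TPM. On the whole chromosome 8 of 580 genes were called (Fisher's exact test p = 0.547). With median-of-ratios scaling the same exact test within 10 Mb gave p = 0.048.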

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

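The fit on recovered reads (voom) was chosen after seeing the data; all other alternatives were planned. The count tests planned for a table of raw counts were not run, as the table holds TPM. The 124 called genes (71 up, 53 down) became 44 (23 up, 21 down) with no filter, 74 (45 and 29) at 5 TPM, 76 (46 and 30) without the variance trend, 2447 (1656 and 791) with library weights, 271 (149 and 122) with the replicate block and 70 (39 and 31) by voom. With 1 library left out the total ranged from 16 to 204, rises from 10 to 112 and falls from 5 to 92. The lowest total was without grna+/+ replicate 3 and the highest without grna+/+ replicate 1. The cause was not tested; leaving out a fish also lowers the degrees of freedom. Library weights rest on 3 fish per group, and the weighted count was not used. grna kept its direction in all settings, from -1.07 to -0.97 with 1 library left out, though its adjusted p rose above 0.05 without grna+/+ replicate 3 or any 1 grna-/- fish. Beyond the calls printed beside their results, the block changed no other call of a list or of a gene named by the rule. Lists called numbered 6 after quantile normalization and 0 with an estimated correlation or fry. At an estimated correlation the adjusted p was 0.595 for the neutrophil, erythroid and inflammatory lists and 0.658 for the cell cycle list; fry gave 0.307, 0.131, 0.307 and 0.307. These tests allow for genes that move together, which the preset value does little to cover. Library weights gave 0.0948 for the cell cycle list, 0.0796 for the endothelial list, and turned the stromal list to the other direction, uncalled (0.989). The erythroid median fell to 0.479 with library weights (adjusted p = 0.000212), that of the cell cycle list to 0.226 and that of the unfolded protein response list to -0.126. They called the interferon (0.00157), immediate early (0.00381) and T cell (0.0393) lists. Medians of lists that stayed called also moved: that of the liver and pancreas list was -1.441 at a pseudocount of 0.1 and -0.449 at 5, that of the stromal list -0.234 at 5, that of the inflammatory list -1.169 without grna+/+ replicate 1, that of the unfolded protein response list -0.315 without the same library, and that of the ribosomal protein list -0.147 with median-of-ratios scaling and -0.011 after rescaling without the 20 most abundant genes. The thrombocyte list was called without members of other lists (0.00923) and after rescaling without the 20 most abundant genes (0.0321). The myeloid transcription factor list was called without members of other lists (0.000233) and, with 1 library left out, ranged from 0.0397 (without grna+/+ replicate 2) to 0.301. The position test ranged from 0.048 (median-of-ratios scaling) to 1 over its alternatives. Of the 121 other named genes tested, none changed direction with a call; over 18 settings 166 calls were lost and 94 gained. At this depth, 11080875 to 14075134 reads, and 3 fish per group, 20% of simulated 2-fold rises and 80% of 4-fold rises were called; depth itself was not varied.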

Other observations

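The genes in this paragraph were picked after their values were seen, and all passed in limma. Beside the rise of dio2, dio3b, the deiodinase that inactivates thyroid hormone, fell from 3.26 to 0.288 TPM, and the retinoid X receptor gene rxrga fell from 38.7 to 13.8 TPM (adjusted p = 0.0356 and 0.0236). The bile acid enzyme hsd3b7 fell (adjusted p = 0.0193) where cyp7a1 rose. The retinal reductase gene dhrs3a fell from 9.96 to 2.40 TPM and the retinol binding protein gene rbp5 from 24.4 to 11.6 TPM (adjusted p = 0.031 and 0.0365). The muscle atrophy ubiquitin ligase gene fbxo32 rose from 2.71 to 8.51 TPM, the Myc antagonist gene mxi1 from 35.7 to 73.5 TPM and the repressor gene hbp1 from 7.94 to 18.5 TPM (adjusted p = 0.0449, 0.027 and 0.0457). gig2q rose from 2.27 to 7.37 TPM (adjusted p = 0.041), against the falls of gig2j and gig2g of the same family. The leukotriene B4 receptor gene ltb4r fell from 474 to 209 TPM, the cell survival gene mcl1b from 671 to 384 TPM and the transcription factor gene ets1 from 136 to 61.2 TPM (adjusted p = 0.0457, 0.0373 and 0.0457).

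All tests below were chosen after the results were seen. The erythroid list was higher in grna-/- with a lower quartile of its members at 0.40. A few abundant genes taking the reads are argued against, since the share of the 20 most abundant genes other than ba1l and hbaa1 could raise the other genes by at most 0.047 (log2) between any pair of libraries. A lower share of neutrophils raising every other lineage alike was not settled. In 7 of the lists of 10 other cell types the upper quartile lay below that lower quartile. The erythroid list had the highest median of the 25 lists tested, so other lists were likely to lie below it whatever the cause. The upper quartiles of the macrophage, cytotoxic and kidney lists lay above that lower quartile. The 10 medians ran from -0.435 in the stromal list to 0.255 in the cytotoxic list. Mature red cells left from the circulation stay open: cell cycle genes, which they would dilute, lay 0.31 above the median of all genes, but within the spread between fish (camera p = 0.327 with an estimated correlation). An effect of genotype on erythroid cells, or a difference between these fish that only happens to follow genotype, may remain and was not tested.

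The 12 largest rises among named genes had a lowest log2 fold change of 1.91. More kidney tubule in the grna-/- libraries was weighed as their whole common cause. The 29 tubule members of the kidney list had an upper quartile of 0.627 and a median of 0.21. The 12 genes were picked as the largest rises, so a preset list was likely to lie below them whatever the cause. Tubule content may still set part of their level: in 9 of the 12 genes the grna-/- libraries stood in the order of their tubule level (0.024, 0.745 and -0.387 in replicates 1 to 3, log2 from the mean of all libraries). Genes move together and 3 libraries have few possible orders, so the 9 matches are not separate observations and can arise by chance. The tubule level was 0.02, 0.194 and -0.595 in grna+/+. All 12 genes were lower in every grna+/+ library than in any grna-/- library, but the rule that named them required this. The rule did not use the tubule level, which was higher in grna+/+ replicates 1 and 2 than in grna-/- replicate 3. The lowest tubule level was in grna+/+ replicate 3 and the highest in grna-/- replicate 2. As measured by these 29 members, tubule content is argued against as the whole cause of the 12 rises, but not as part of it. A local effect of variants linked to grna is argued against, since 1 of the 12 genes lay on its chromosome in assembly GRCz12tu. Variants acting at a distance, feeding or time of day could also differ between fish and were not tested, nor was genotype apart from them.

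All 7 vitellogenin genes had lower mean TPM in grna-/-, and vtg6 and vtg4 fell (vtg4 from 4.44 to 0.58 TPM, limma adjusted p = 0.0425). Their copies share sequence, so single levels are uncertain. Liver left in the grna+/+ libraries cannot be told apart from a change in the marrow: 5 of 6 liver members were lower, with a median of -1.11. apoa2 was higher on average through grna-/- replicate 2 alone (11.49 TPM, against 0.55 and 0.83 TPM in replicates 1 and 3). It did not pass (limma adjusted p = 0.486). Fish of another sex in the 2 genotypes is a candidate explanation that stays open, since no label gives the sex and only 1 gonad list member, sycp1, was tested. An effect of genotype was not tested apart from these.

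The 6 libraries make 10 splits into 3 and 3, too few for a share below 0.05. The real split called 124 genes, and the highest of the others 2, so 1 of 10 splits reached the real count. Among the 4 splits that part all 3 numbered pairs, the block gave 271 genes for the real one and 0 for each of the other 3, which each exchange the fish of 1 pair. For the lists the real split called 10 and the highest other 12, and 4 of 10 splits called as many as the real one.

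The grna+/+ replicate 2 library stood apart, at -47.7 on the first principal component (48.5% of the variance) against -5.5 and -23 for the other grna+/+ libraries and 22.9 to 28.5 for grna-/-. It held 4089 TPM of mmp9, against 608 and 1021 TPM in the other grna+/+ libraries.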
